A study of Danio rerio with 6 samples.

How the data were processed

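RNA from trunks of zebrafish larvae at 72 h after fertilisation was measured on 6 single-colour Agilent arrays of the OakLabs Zebrafish ArrayXS design, labelled with Cy3. Per the labels' protocols, larvae were raised at 28 °C with 40 per dish, heads were taken off for genotyping, trunks were lysed singly, and lysates of at least 10 larvae of 1 genotype were then combined. The 3 homozygous pools carried the s983 allele of murcb on both chromosomes and the 3 heterozygous pools carried it on 1 chromosome. Groups came from the genotype label. A description label calls the heterozygous pools wild type, and the genotype given in the titles, in the characteristics and in the series design was used.

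The deposited spot intensities came from Agilent Feature Extraction 11.5.1.1, with background subtraction, spatial detrending and surrogate values for spots not above background, per the file headers. They are linear processed intensities, not scaled between arrays. The deposited table of the authors' processed values holds linear intensities with the same quantiles in all 6 columns (median 297.6 in each), and its ranks followed the scanner values on every array. The step that made it is not given in the sources used here, and it served as an alternative only.

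Each array held 61657 non-control spots for 60022 probes and 1319 control spots. Control spots were left out, as were between 9 and 27 spots per array with an outlier flag. No spot was saturated. Between 93.8% and 96.7% of the probes per array were well above background. The number of arrays limits the precision. All 6 arrays lay on 1 slide and were scanned together. The mutant pools filled slide row 1 and the heterozygous pools row 2, so slide row and genotype cannot be told apart. Each replicate number filled 1 slide column.

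The main values were log2 of the processed intensity minus the array's 75th percentile, with spots of a probe averaged. Probes well above background on all 3 arrays of at least 1 genotype were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over 56816 probes and a threshold of 0.05. An exact permutation test of 3 against 3 could not give a p below 0.1. No label says whether the pools of a genotype came from separate crosses, so the p-values measure only the spread between these pools. A probe not well above background on any array of 1 genotype has only a bound there. Its fold is given as at least the ratio of the other genotype's mean to the mean of, per array, the higher of its own signal and the lowest signal among probes well above background.

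Positions are those of the array design on Zv9 (danRer7). Transcript accessions and older names were brought up to date through a RefSeq gene table (assembly GRCz12tu, used for names only). A name was found for 46431 probes and 13591 stayed unnamed. A gene with several tested probes is given by its brightest probe. Of 12217 such genes, 6831 had all probes on the same side of 0 and 5386 had probes on both sides.

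The 35 gene lists were tested with camera at a preset correlation of 0.01, and adjusted over the lists. They covered caveolae and muscle structure, metabolism, stress and signalling, and markers of cell types that a trunk can hold or that head tissue left on it would bring. Lists for ribosomal proteins, proteasome, respiratory chain and lens took in symbol patterns, and the ribosomal pattern also took in S6 kinase genes and rpl7l1. Lists, tests, naming rule and most alternatives were fixed before the data were examined. The rule named murcb, murca, up to 4 members of each list with the smallest adjusted p and, since no gene passed, the 6 genes with the smallest p in each direction. The text gives only some of the list members so named. Genes on the chromosome of murcb were set against the rest by Fisher's exact test, two-sided.

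The genotypes share replicate numbers in the labels. After subtraction of genotype means, arrays with the same number correlated across probes at 0.622, 0.427 and 0.738 for numbers 1, 2 and 3, and arrays with different numbers at -0.725 to -0.115. The deviations of a genotype cancel out in each probe, so positive same-number correlations force negative ones elsewhere, which are no separate evidence. The numbers were taken from the same-number correlations to pair the pools. The labels do not say what a number stands for.

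Alternatives were normexp background correction with an offset of 50, median scaling, quantile normalization, the authors' values, no filter or a stricter filter on dim probes, a trended robust variance, kept outlier spots, a 1.5-fold minimum, the replicate block and leaving out each array. Set tests were also run with an estimated correlation, with fry and with the mean over a gene's probes. Added after seeing the data were the block with a pair left out, array weights, quantile normalization with the block, removal of a trend with probe GC content with and without the block, an estimated correlation with the block, and a chromosome test at an unadjusted p under 0.01.

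The fit was tested on 5 simulated sets of 56816 probes. It called 10.8%, 60.8%, 82.0% and 96.0% of 250 probes changed by 1, 2, 3 and 4 on the log2 scale, with 29 false calls. With the block it called 0%, 56.8%, 73.6% and 86.0%, with 8 false calls. The sets for the block were drawn separately and held the replicate-number effects of the data. Those for the fit without the block held them only as independent noise, so the rates do not rank the fits. A list of 40 random probes shifted by 0.3 had an unadjusted camera p under 0.05 in 5 of 5 sets, and an unshifted list in 0. The simulated noise was independent between probes, and this p was not adjusted over lists. Members of a real list can move together, so these counts say little about the power or false calls of the list test.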

Results

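Expression in the trunk of zebrafish larvae homozygous for a mutation in murcb was compared with that of heterozygous siblings at 72 h after fertilisation. The gene murcb (now cavin4b) encodes a muscle cavin, a coat protein of caveolae, which are small pits of the muscle cell membrane. Its paralog is murca (now cavin4a). Each of the 3 homozygous mutant and 3 heterozygous samples was a pool of at least 10 trunks, hybridised to 1 array. Median probe intensity was 358.2, 302.7 and 228.5 for heterozygous replicates 1, 2 and 3, and 323.0, 274.2 and 247.1 for the mutant replicates. Unless stated otherwise, levels are log2 intensities relative to the array's 75th percentile, differences are mutant minus heterozygous, and n = 3 pools per genotype.

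The first question was which transcripts differ in the trunk when murcb is mutated. No transcript passed the test in either direction. The difference with the smallest p was that of stoml3a, a gene of the stomatin family of membrane proteins, whose mean was 2.34 higher in the mutant pools. Among the genes with lower means were crp2, crp3 and crp7, members of the C-reactive protein family of acute-phase proteins, and the cathepsin genes cts12 and ctskl. With limma, 0 of 56816 probes, standing for 22864 named genes, were higher and 0 were lower. At an unadjusted p under 0.05 there were 694 probes, where 2841 would be reached by chance, and with the replicate number as a block there were 4596, again with 0 past the threshold. The median standard error was 0.23, and 0.154 with the block. The fit without the block leaves the spread between replicate numbers in its error. Its SEs, intervals and p-values, given below unless the block is named, include that spread.

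The mutated gene itself was measured by 1 probe for transcript ENSDART00000079292 (chromosome 24, 34959506 to 34965880). The murcb level was 2.499 ± 0.16 (SD, n = 3) in the heterozygous and 2.47 ± 0.04 in the mutant pools, a difference of -0.03 with a 95% confidence interval of -0.42 to 0.37 (adjusted p = 1). The sign of this difference turned with quantile normalization, where it was 0.002. Where the s983 change lies relative to the murcb probe is not given in the sources used here, so this level checks the genotype labels little. The paralog murca (ENSDART00000144716, chromosome 2, 42292710 to 42299718) stood at 2.07 ± 0.03 in the heterozygous and 1.76 ± 0.15 in the mutant pools. Its difference was -0.31 with an interval of -0.70 to 0.09 (adjusted p = 1), and the murca level of each mutant pool lay below each heterozygous pool.

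Under the naming rule, the 6 genes with the smallest p and a higher mean were stoml3a, lrriq3, macrod1, si:dkey-4c23.8, prf1.7 and si:dkey-30j22.12. The level of stoml3a (chromosome 15, 3355194 to 3361980) was -5.19 ± 0.14 in the heterozygous and -2.85 ± 0.22 in the mutant pools (SE of the difference 0.19, adjusted p = 0.177). The leucine-rich repeat gene lrriq3 and the ADP-ribose hydrolase gene macrod1 were not well above background on any heterozygous array, and the mutant mean of each was at least 2.19-fold higher than the bound (adjusted p = 1 for both). The differences of si:dkey-4c23.8 and the perforin gene prf1.7 were 0.96 (SE 0.22) and 1.06 (SE 0.27), each with 1 of 3 heterozygous arrays well above background, and that of si:dkey-30j22.12 was 1.11 (SE 0.28), with an adjusted p of 1 for all of these.

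The 6 genes with a lower mean that the rule named for their p were nitr1a, cts12, crp3, ctskl, crp7 and crp2, all with an adjusted p of 1. The immune-type receptor gene nitr1a was not well above background on any mutant array and was at least 3.56-fold lower in the mutant pools. The difference of cts12 was -1.29 (SE 0.30) and that of ctskl -1.04 (SE 0.24). Both are annotated from the same start on chromosome 22 (16628896), so their probes can measure overlapping transcripts. The differences were -1.23 (SE 0.28) for crp3, -1.23 (SE 0.30) for crp7 and -1.24 (SE 0.32) for crp2. These 12 genes kept their sign under every alternative run. They were picked for no overlap between the genotypes, which fixes the sign when arrays or pairs are left out or weighted. Only the alternatives in background correction, scaling or GC trend could have turned it. With normexp, which compresses dim spots, the differences were 1.23 for stoml3a, 0.32 for lrriq3, 0.29 for macrod1, 0.32 for si:dkey-4c23.8, 0.28 for prf1.7, 0.47 for si:dkey-30j22.12, -0.38 for nitr1a, -0.64 for cts12 and -0.46 for ctskl.

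**Figure D1:**
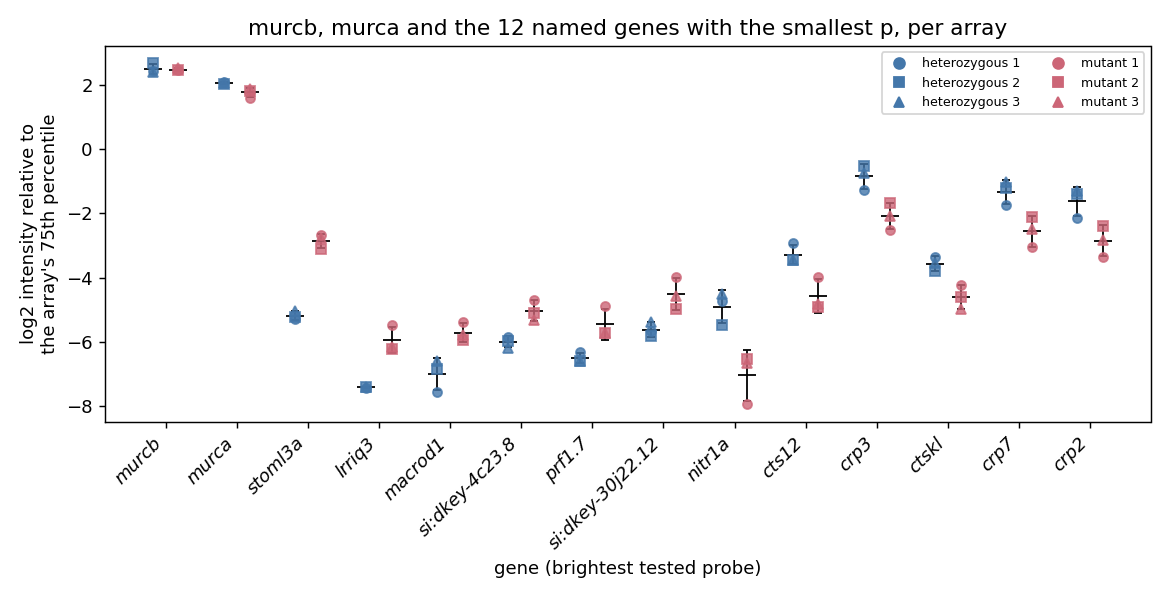
Log2 intensity relative to the array's 75th percentile (vertical axis) of murcb, murca and 12 named genes, per array. The 12 are the 6 in each direction with the smallest p among genes without overlap between the genotypes. Symbols show the replicate number, with blue for heterozygous and red for mutant pools, and bars the mean and SD of 3. The murcb symbols overlap, while stoml3a lies near -5.19 in the heterozygous and -2.85 in the mutant pools.

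Gene lists chosen for muscle and its surroundings came next. No member of any of the 35 lists passed, either over all genes or adjusted over the list alone, and no list passed camera. Genes of caveola coats and their partners had a median difference of -0.04 over 17 genes (adjusted p = 0.686). Among them were the cavin1 homolog ptrfa at -0.36 (SE 0.17) and the membrane-bending pacsin2 at 0.38 (SE 0.35). The caveola median ran from -0.173 without mutant replicate 3 to 0.115 without heterozygous replicate 3, passing in neither. The T-tubule and excitation-contraction list had a median of -0.03 over 35 genes (adjusted p = 0.980), with the phosphoinositide phosphatase mtm1 at 0.62 (SE 0.27) and the calcium channel subunit cacnb1 at -0.41 (SE 0.29). The dystrophin, costamere and Z-disc list had a median of -0.07 over 51 genes (adjusted p = 0.431), with filamin flnca at -0.43 (SE 0.19) and dystrobrevin dtnba at -0.36 (SE 0.19). Fast muscle contractile genes had a median of -0.08 over 44 genes (adjusted p = 0.225), with the alpha-actinin gene actn3a at -0.29 (SE 0.18). Myogenic regulators had a median of -0.02 over 34 genes (adjusted p = 0.905), with myf6 at 0.67 (SE 0.35) and the myosin chaperone-associated smyd1b at -0.36 (SE 0.21).

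In the slow muscle list, 23 of 28 genes lay below 0, with a median of -0.10 (adjusted p = 0.111). The regulator of slow fibre fate prdm1a was at -0.75 (SE 0.34), the slow troponin T gene tnnt1 at -0.39 (SE 0.20) and myoglobin, mb, at -0.78 (SE 0.58). With the replicate block the slow muscle list passed (adjusted p = 0.04995), at medians of -0.20, -0.03 and -0.09 in pairs 1, 2 and 3. Its adjusted p there was 0.999 with an estimated correlation. The slow muscle list also passed camera downward with normexp (adjusted p = 0.0340) and with the mean over a gene's probes (adjusted p = 0.0411). The slow muscle median turned to 0.028 without mutant replicate 1 (camera adjusted p = 0.865). It was -0.014 without heterozygous replicate 3 (adjusted p = 0.252) and -0.194 without mutant replicate 3 (adjusted p = 0.00285). Heart markers had a median of -0.06 over 23 genes (adjusted p = 0.672), with the potassium channel gene kcnh6a at -0.76 (SE 0.42) and the sodium-calcium exchanger gene slc8a1a at 0.22 (SE 0.21). Muscle chaperone, atrophy and autophagy genes had a median of -0.09 over 52 genes (adjusted p = 0.326), with the protease gene capn3b at -0.47 (SE 0.19) and fbxo30a at 0.74 (SE 0.42). Tendon and myosepta markers had a median of -0.04 over 18 genes (adjusted p = 0.951), with mkxa at 0.61 (SE 0.38) and fibina at -0.19 (SE 0.26). Extracellular matrix and fibrosis genes had a median of -0.08 over 75 genes (adjusted p = 0.686), with laminin lamc1 at 0.48 (SE 0.20) and collagen col4a2 at 0.52 (SE 0.31). Notochord and cartilage markers had a median of -0.10 over 30 genes (adjusted p = 0.260), with the cartilage matrix genes matn3b at 0.44 (SE 0.25) and col9a1a at -0.37 (SE 0.22).

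Among metabolic and growth genes, the list nearest to the threshold was the mitochondrial respiratory chain. There 83 of 101 genes lay below 0, with a median of -0.10 (adjusted p = 0.0649), and examples were ndufs1 at -0.37 (SE 0.20), ndufb10 at -0.36 (SE 0.23) and, on the other side, ndufs8b at 0.51 (SE 0.20). With the block the respiratory chain list passed (adjusted p = 0.0448), at medians of -0.25, 0.08 and -0.16 in pairs 1, 2 and 3. Its adjusted p there was 0.999 with an estimated correlation. The respiratory chain list also passed camera downward with normexp (adjusted p = 0.00203) and with the mean over a gene's probes (adjusted p = 0.00501). The respiratory chain median was above 0, at 0.040, without mutant replicate 1 (camera adjusted p = 0.491). It was 0.037 without heterozygous replicate 3 (adjusted p = 0.772) and -0.198 without mutant replicate 3 (adjusted p = 6.53e-07). Glycolysis and glycogen genes had a median of -0.15 over 40 genes (adjusted p = 0.0768), with lactate dehydrogenase ldha at -0.45 (SE 0.17), enolase eno1a at -0.29 (SE 0.17) and the glucose transporter gene slc2a1a at 0.49 (SE 0.28). Hypoxia response genes, which share ldha, had a median of -0.13 over 28 genes (adjusted p = 0.322), with erythropoietin, epoa, at -0.86 (SE 0.42) and ankrd37 at 0.53 (SE 0.28). Cell cycle genes had a median of -0.10 over 42 genes (adjusted p = 0.0768), with cyclin ccne2 at -0.74 (SE 0.38) and the ribonucleotide reductase gene rrm1 at -0.52 (SE 0.32). The glycolysis and cell cycle lists passed camera downward with normexp (adjusted p = 0.00637 and 0.0176). They did so with the mean over a gene's probes too (adjusted p = 0.0140 and 0.0233).

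Cholesterol and lipid genes had a median of -0.05 over 46 genes (adjusted p = 0.980), with the sterol synthesis gene msmo1 at 0.59 (SE 0.24) and the fatty acid receptor gene cd36 at -0.47 (SE 0.32). The circadian clock list had a median of -0.03 over 38 genes (adjusted p = 0.686), with cry5 at -0.75 (SE 0.41) and nr1d2a at 0.61 (SE 0.38). Cytosolic ribosomal proteins had a median of -0.03 over 90 genes (adjusted p = 0.431), and the members with the smallest p were the S6 kinase gene rps6ka1 at -0.34 (SE 0.22) and rpl7l1 at -0.25 (SE 0.19), neither of which encodes a ribosomal subunit protein. Proteasome subunits had a median of -0.09 over 44 genes (adjusted p = 0.196), with the immunoproteasome gene psmb8a at 0.64 (SE 0.32) and psmd5 at -0.35 (SE 0.19). Unfolded protein response genes had a median of -0.09 over 28 genes (adjusted p = 0.194), with pdia6 at -0.29 (SE 0.19) and creld2 at 0.20 (SE 0.16).

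Signalling and stress lists gave similarly small values. Targets of ERK and FGF feedback had a median of -0.10 over 35 genes (adjusted p = 0.260), with mapk3, an ERK kinase gene and so not a feedback target, at -0.66 (SE 0.39) and the phosphatase dusp5 at -0.31 (SE 0.18). Immediate early genes had a median of -0.01 over 37 genes (adjusted p = 0.686), with atf3 at 0.90 (SE 0.53). Inflammation and acute-phase genes had a median of 0.05 over 33 genes (adjusted p = 0.296), with serum amyloid, saa, well above background on 1 of 3 heterozygous arrays, at 0.55 (SE 0.25). The interferon list had a median of -0.05 over 28 genes (adjusted p = 0.855), with cmpk2 at -0.48 (SE 0.20) and mxa at 0.34 (SE 0.19). The p53 target list had a median of -0.04 over 18 genes (adjusted p = 1), with mdm2 at 0.56 (SE 0.36), bbc3 at 0.84 (SE 0.48) and phlda3 at -0.23 (SE 0.19).

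Markers of other cell types were read in the same way. In the eye and lens list, 59 of 100 genes lay below 0, with a median of -0.06 (adjusted p = 0.199), and photoreceptor genes gngt1 and rom1b stood at -0.55 (SE 0.21) and -0.85 (SE 0.41). The eye and lens median was -0.32 (adjusted p = 8.72e-08) without heterozygous replicate 3 and -0.15 (adjusted p = 1.09e-05) without mutant replicate 1, and above 0, at 0.03, without mutant replicate 2 (adjusted p = 0.971). With the block this list passed (adjusted p = 0.0401), at medians of -0.16, -0.50 and 0.04 in pairs 1, 2 and 3, and its adjusted p was 0.999 with an estimated correlation. Brain and head markers had a median of -0.08 over 44 genes (adjusted p = 0.225), with the otolith matrix gene stm at -0.61 (SE 0.29). Another member, pomcb, well above background on 1 of 3 heterozygous arrays, was at 0.80 (SE 0.39). Neuron and glia markers had a median of -0.09 over 51 genes (adjusted p = 0.277), with sox10 at -0.28 (SE 0.21) and the myelin gene plp1b at 0.48 (SE 0.34). Epidermis and ionocyte markers had a median of -0.01 over 48 genes (adjusted p = 0.686), with foxi3a at 0.51 (SE 0.27) and the keratin krt93 at -0.26 (SE 0.22). Macrophage and neutrophil markers had a median of -0.03 over 33 genes (adjusted p = 1), with the leukocyte phosphatase ptprc at 0.62 (SE 0.34) and the transcription factor gene spi1a at -0.36 (SE 0.42).

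Liver markers had a median of -0.09 over 38 genes (adjusted p = 0.596), with the glucose-6-phosphatase gene g6pc1a.1 at -0.48 (SE 0.30) and cyp3a65 at 0.72 (SE 0.41). The liver median was -0.35 (adjusted p = 0.00264) without heterozygous replicate 1 and 0.20 (adjusted p = 0.317) without mutant replicate 1, and over all 6 arrays the adjusted p was 1 with an estimated correlation. Intestine and exocrine pancreas markers had a median of -0.10 over 39 genes (adjusted p = 0.199), with the chymotrypsinogen gene ctrb.3 at -0.66 (SE 0.26) and the trypsin gene prss1 at -0.42 (SE 0.25). Kidney tubule markers had a median of -0.02 over 30 genes (adjusted p = 0.783), with pax8 at 1.43 (SE 0.72) and evx1 at -0.34 (SE 0.20). Endothelial markers had a median of -0.04 over 36 genes (adjusted p = 0.905), with flt4 at 0.85 (SE 0.49). Erythroid markers had a median of 0.05 over 26 genes (adjusted p = 0.956), with the haem synthesis gene alas2 at -0.29 (SE 0.24) and rhag at 0.27 (SE 0.27).

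The levels of several marker lists differed more between replicate numbers than between genotypes. Neuron and glia markers, centred on the mean of the 6 arrays, stood at 0.52 and 0.35 in heterozygous and mutant replicate 1 and at -0.43 and -0.46 in replicate 3, and liver markers at -0.36 and -0.38 against 0.56 and 0.21. Mutant replicate 1 also stood apart, at -116.5 on a first principal component that held 51.0% of the variance, where the other arrays lay between -37.1 and 59.8. Leaving it out moved the differences of 77 of the 149 genes named by the rule by over 1.5 times, and leaving out mutant replicates 2 and 3 moved 37 and 34, heterozygous replicates 1, 2 and 3 moved 28, 10 and 24.

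Of the examples given, those that moved by over 1.5 times are named here by the array left out. Without mutant replicate 1 the differences nearer to 0 were those of flt4 (0.28), pax8 (0.63), bbc3 (0.30), mdm2 (0.19), mkxa (0.18), nr1d2a (0.18), col4a2 (0.18), myf6 (0.31), psmb8a (0.29), ptprc (0.25), foxi3a (0.29), mtm1 (0.39), alas2 (-0.08), sox10 (-0.14), ndufb10 (-0.17), ndufs1 (-0.22), smyd1b (-0.19), actn3a (-0.17), rpl7l1 (-0.13), plp1b (0.12), pomcb (0.36), matn3b (0.21), slc8a1a (0.09), fbxo30a (0.30), fibina (-0.07), ankrd37 (0.32), slc2a1a (0.28), psmd5 (-0.22), krt93 (-0.17), cyp3a65 (0.30) and rhag (0.16). There spi1a turned to 0.08 and mb lay farther from 0 (-1.19). Without mutant replicate 2 the differences farther from 0 were those of stm (-0.92), pacsin2 (0.64), rrm1 (-0.79), nr1d2a (0.98), rps6ka1 (-0.52), flt4 (1.34), mapk3 (-0.99), atf3 (1.38), prss1 (-0.63), pax8 (2.27), ptprc (0.95), myf6 (1.01), sox10 (-0.45), bbc3 (1.34), mdm2 (0.91), cacnb1 (-0.64), mkxa (0.94), plp1b (0.82), fbxo30a (1.17), fibina (-0.47), krt93 (-0.47), spi1a (-0.74), cyp3a65 (1.12) and rhag (0.50). Without mutant replicate 3, stm (-0.35), pacsin2 (0.11), rrm1 (-0.32), mapk3 (-0.44), kcnh6a (-0.50), atf3 (0.52), ctrb.3 (-0.42), prss1 (-0.23), mb (-0.46), cacnb1 (-0.27), fibina (-0.05), cd36 (-0.24), krt93 (-0.13) and rhag (0.16) lay nearer to 0. Without heterozygous replicate 1, pacsin2 (0.21), rrm1 (-0.34), rps6ka1 (-0.22), dusp5 (-0.18), rom1b (-0.47), tnnt1 (-0.25), mb (-0.16), cacnb1 (-0.26), ankrd37 (0.34), cd36 (-0.18), phlda3 (-0.15), evx1 (-0.21) and rhag (0.18) lay nearer to 0, and spi1a (-0.59) farther from it. Without heterozygous replicate 2, g6pc1a.1 (-0.72), col9a1a (-0.56) and phlda3 (-0.35) lay farther from 0, and slc8a1a (0.10), slc2a1a (0.29) and rhag (0.17) nearer to it. Without heterozygous replicate 3, alas2 (-0.17), g6pc1a.1 (-0.17) and spi1a (-0.18) lay nearer to 0, and pacsin2 (0.66), mapk3 (-1.01), kcnh6a (-1.15), atf3 (1.37), cacnb1 (-0.66), slc8a1a (0.34) and rhag (0.46) farther from it. With normexp, cd36 (-0.29), slc2a1a (0.26), slc8a1a (0.14), ankrd37 (0.24), pomcb (0.28), saa (0.22), cmpk2 (-0.17), mxa (0.18), spi1a (-0.13) and ndufs8b (0.30) lay nearer to 0. For some examples another tested probe lay on the other side of 0, reaching 0.59 for epoa, 0.61 for dtnba, 0.33 for cacnb1, 0.19 for rps6ka1, 0.11 for mapk3, 0.12 for alas2, 0.14 for evx1, 0.04 for g6pc1a.1 and 0.11 for spi1a, and -0.24 for atf3, -0.29 for mdm2, -0.15 for pacsin2, -0.05 for nr1d2a, -0.18 for rhag, -0.02 for col4a2, -0.03 for fbxo30a, -0.15 for plp1b and -0.22 for creld2.

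With an estimated correlation in camera every list had an adjusted p of 1. At the preset correlation, 5 lists passed with normexp, all downward: cell cycle, glycolysis, respiratory chain, slow muscle and unfolded protein response. Taking the mean over a gene's probes, 7 passed, all downward: cell cycle, eye, glycolysis, intestine, respiratory chain, proteasome and slow muscle. Without heterozygous replicate 1, 7 lists passed, all downward: ribosomal, epidermis, fast and slow muscle, liver, macrophage and respiratory chain. Without heterozygous replicate 2, 4 passed downward, namely glycolysis, intestine, respiratory chain and proteasome. Without heterozygous replicate 3, the brain, cell cycle, eye and neuron lists passed downward and the epidermis, inflammation and macrophage lists upward. Without mutant replicate 1, the brain, cell cycle, eye, intestine and neuron lists passed downward and the ribosomal, epidermis, matrix, inflammation and macrophage lists upward. Without mutant replicate 2, the cell cycle list alone passed, downward, and without mutant replicate 3 the ribosomal, fast and slow muscle, glycolysis and respiratory chain lists did, downward. Median and mean differed in sign for the cholesterol, circadian, endothelial, epidermis, immediate early, kidney, myogenic, p53 and T-tubule lists, the tendon mean was 0, and the macrophage list had a negative median with an upward camera direction. Another background or scaling setting turned the sign of the median for the erythroid, inflammation, epidermis, endothelial, immediate early, kidney and macrophage lists.

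**Figure D2:**
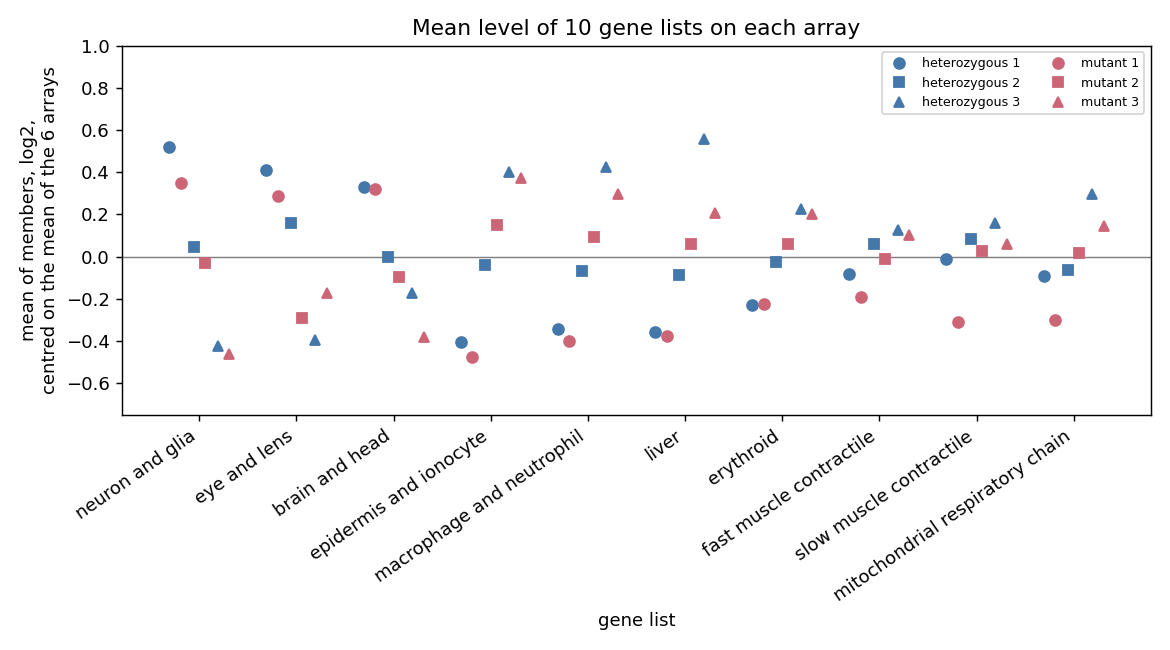
Mean log2 level of 10 gene lists on each array, centred on the mean of the 6 arrays (vertical axis), with circles, squares and triangles for replicate numbers 1, 2 and 3, blue for heterozygous and red for mutant pools. Neuron and glia markers lie at 0.52 and 0.35 in replicate 1 and at -0.43 and -0.46 in replicate 3, with the genotypes of each number side by side.

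Siblings sorted by genotype at murcb also differ in the DNA linked to it, so genes on chromosome 24 were set against all others. At the test's threshold the count was 0 of 658 genes on chromosome 24 and 0 of 22206 elsewhere (Fisher's exact p = 1). Since no gene passed anywhere, this outcome was fixed and says nothing about enrichment. At an unadjusted p under 0.01, a threshold chosen after seeing the data, there were 7 of 1545 probes on chromosome 24 (0.453%) and 69 of 54586 elsewhere (0.126%), an odds ratio of 3.60 (Fisher's exact p = 0.00496). With the replicate block the shares were 1.75% and 0.995% (odds ratio 1.77, Fisher's exact p = 0.00649). Within 5 Mb of murcb the block had 15 such probes, and 8 with the crp family left out. So crp probes raised this share too. Of the 7 probes in the fit without the block, 6 lie between 4.63 and 4.68 Mb from murcb in the crp cluster. Among these, 2 have the same probe sequence, so they are not independent. The other of the 7 measures ENSDART00000123296 (chromosome 24, 38390608 to 38406841, 3.43 Mb away), an unnamed transcript chosen after its values were seen. It was not well above background on any mutant array and at least 3.88-fold lower there (adjusted p = 0.672).

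**Figure D3:**
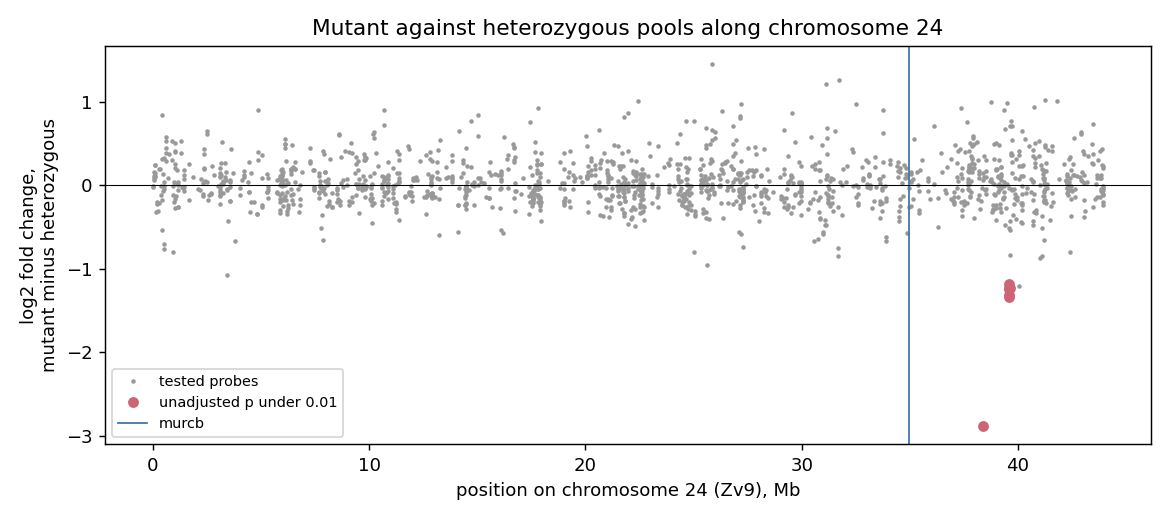
Log2 difference between mutant and heterozygous pools (vertical axis) of each tested probe along chromosome 24 in Mb (horizontal axis, Zv9), with the 7 probes at an unadjusted p under 0.01 in red and murcb as a blue line. The red probes lie between 3.43 and 4.68 Mb from murcb, and that for ENSDART00000123296, drawn at its measured difference, has only a bound of at least 3.88-fold since no mutant array was well above background.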

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

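The replicate block with a pair left out, array weights, quantile normalization with the block and removal of a GC trend were chosen after the results were seen. The count of probes past the threshold stayed at 0 in every alternative fixed beforehand, including each array left out (346 to 5830 probes at an unadjusted p under 0.05). Of the added ones, the block gave 1 higher and 6 lower without pair 1, 0 and 0 without pair 2, and 4 and 7 without pair 3, array weights gave 1 and 0, and quantile normalization with the block 1 and 1. The gene stoml3a was called in each that made calls (adjusted p 0.000362 to 0.0485), and ENSDART00000123296 in those with the block. On chromosome 24 the block also called, as lower, ENSDART00000122618 (3.46 Mb from murcb) without pair 1 (adjusted p 0.00105) and an lyrm1 probe (6.12 Mb) without pair 3 (adjusted p 7.49e-05). Neither probe was tested over all 6 arrays or was well above background on any mutant array. Over all alternatives the stoml3a difference ran from 1.23 to 2.46 (adjusted p 0.000362 to 1). The lower end came with normexp. Array weights were 4.17 for heterozygous replicate 2 and 2.7 for mutant replicate 3, against 0.27 to 0.75 for the others. That fit mostly set these pools of different replicate numbers against each other. A pair left out leaves few residual degrees of freedom, so those p-values lean on the variance pooled over probes. They are no stronger evidence than the limma fit with the block over all 6 arrays, whose smallest adjusted p was 0.161.

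The murcb difference was -0.12 to 0.08 and above 0 with quantile normalization (0.002, also with the block), the authors' values (0.003), without heterozygous replicate 2 (0.066, down to -0.079 without heterozygous replicate 3) and with the block without pair 2 (0.078), while murca stayed between -0.36 and -0.20. The sign also turned for creg1 with array weights (0.127), havcr1 without mutant replicate 1 (0.089, down to -0.513 without mutant replicate 3) and with array weights (0.060), and spi1a without mutant replicate 1 (0.076, down to -0.735 without mutant replicate 2). Of 3271 values of 149 named genes, 3262 kept sign and side of the threshold. These genes were picked for small p in these same data, and none passed in the main setting. That count was thus largely fixed beforehand and says little about stability. Sizes moved more: without mutant replicate 1, 77 of the 149 changed by over 1.5 times. Normexp compresses dim spots, and leaving out 1 array or weighting the arrays takes away the balance between replicate numbers. The cause of these shifts was not tested.

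No list passed in the main setting, but 5 did with normexp, 3 with the block, 7 with the mean over probes and 1 to 10 with 1 array left out. There were 5, 6 and 1 with the block without pair 1, 2 and 3, 8 with array weights and 1 with quantile normalization and the block. With the GC trend removed, with or without the block, 3 passed downward. These were the eye and lens (median -0.128, against -0.058 in the main setting), respiratory chain (-0.142, against -0.103) and slow muscle lists (-0.196, against -0.099). The direction camera tested turned, past the threshold, without heterozygous replicate 1 for epidermis (median -0.199) and macrophage (-0.160) markers, and without mutant replicate 1 for ribosomal proteins (0.153, and 0.164 with array weights) and extracellular matrix (0.096). With 1 array left out, medians ran from -0.199 to 0.281 for epidermis, -0.177 to 0.178 for macrophage, -0.161 to 0.153 for ribosomal and -0.150 to 0.096 for matrix genes. They ran from -0.374 to 0.161 for neuron and glia, -0.321 to 0.025 for eye and lens and -0.350 to 0.195 for liver markers. Leaving out 1 array or weighting the arrays unbalances the replicate numbers between the genotypes. Of 910 list values, 709 kept direction and side of the threshold, 71 passed it in the same direction and 125 turned direction without passing it.

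The block changed the call of the slow muscle, respiratory chain and eye and lens lists and of the test of probes near murcb without crp probes (Fisher's exact p 0.328 and 0.0158), and no other call. All 10 splits of the 6 arrays into equal groups, the real one included, gave 0 probes past the threshold (highest other 0), and 10 splits are too few for a share under 0.05.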

Other observations

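The tests of neighbouring spots and of hox genes were set before their results were seen; the tests of linked variants, liver markers, eye and lens markers, slide column, quantile and GC correction and pair differences, and that between replicate numbers, were chosen after.

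Levels of tissue markers differed between the replicate numbers. In a limma test over the numbers, 6356 of 56816 probes (11.2%) differed. Of the neuron and glia markers 21 of 51 differed, all higher in number 1 than in number 3, with a list median of 0.93. Examples were the GABA synthesis genes gad1b (2.15) and gad2 (2.19) and the motor neuron factor isl1a (1.89). In the eye and lens list 25 of 100 differed, all higher in number 1, such as the retinoid isomerase rpe65a (2.23) and the red cone opsin opn1lw2 (1.65). Among brain and head markers 10 were higher and 2 lower, with the forebrain and eye factors six3a (2.00) and six6b (2.07) among the higher.

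Other tissues went the opposite way. Of the epidermis and ionocyte markers 21 of 48 differed, all lower in number 1, with a median of -0.75, such as agr1 (-2.22) and the keratin krt97 (-1.43). Of the liver markers 16 of 38 were lower, with a median of -0.88, such as the macroglobulin gene a2ml (-1.32) and the retinol carrier rbp4 (-1.46). Of the macrophage and neutrophil markers 10 of 33 were lower, such as lysozyme, lyz (-1.24). The median of fast muscle contractile genes was -0.32 with 0 of 44 past the threshold, and that of T-tubule genes -0.07 with 0 of 35.

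The first pattern to follow is this split between numbers. A candidate explanation is head tissue left on some of the trunks of number 1. Its test asked whether hox genes of groups 4 to 13, used behind the head, would go against the head markers. Their median was -0.40 (38 genes, 25 below 0, quartiles -0.75 and 0.07), and 4 of 38 differed, against 11.2% of all probes. Lists not tied to the head varied too, with -0.45 for the respiratory chain, -0.60 for ribosomal proteins and 0.26 for the cell cycle. The hox median thus does not single out head tissue. More spinal cord alone would not raise eye and lens markers, whose median was 0.63. That rise was known before the test was set, and it cannot exclude more spinal cord alongside head tissue. Each of the 3 slide columns held 1 number, so column and number cannot be told apart, and neither clutch nor stage was tested.

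The second is the group of crp genes on chromosome 24, where 6 of 11 probes, picked for their low p, had a median difference of -1.24, while crp6 was at -0.83, the probes of apcs at -0.42 and -0.53, DRER36842, another crp3 probe, at -0.52 and crp1 at -0.03. Less liver, as the whole cause, is argued against by the liver list, at -0.092 (quartiles -0.22 and -0.01), with 0 of 38 genes as low as the crp probes. Still, 29 of the 38 lay below 0, and the liver medians were -0.14, 0.15 and -0.24 in pairs 1, 2 and 3. Over the alternatives the liver median ran from -0.35, without heterozygous replicate 1, to 0.24. A stain on the array is argued against by 133 neighbouring spots, at -0.019. DNA variants linked to murcb could lower them or their probes' binding. Outside the crp family, 1 of 318 probes within 5 Mb of murcb had an unadjusted p under 0.01 against 69 of 55802 elsewhere (Fisher's exact p = 0.328), and with the replicate block 8 against 555 (p = 0.0158), so the result rests on the fit. An effect of the mutation itself on these genes cannot be told apart from linked variants with 1 allele.

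The third is mutant replicate 1, whose deviations had an SD of 0.513 where the other arrays had 0.242 to 0.341. The ratio to the highest of the others was 1.5, and it stayed at 1.53 after quantile normalization and 1.49 after removal of a GC trend, which argues against signal compression and GC content as the whole cause. A genotype effect common to all pairs, as the whole cause, is argued against by pair 2. Across probes its differences correlated at 0.091 with those of pair 1 and at -0.062 with those of pair 3. Pair 2 had the smallest spread of differences (SD 0.245, against 0.568 and 0.322 in pairs 1 and 3), so a weaker common part is not excluded. Pairs 1 and 3 correlated at 0.505, so what they share is not particular to mutant replicate 1. RNA quality and the makeup of that pool stay open and may each contribute.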
